A study of Caenorhabditis elegans with 2 samples.

How the data were processed

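The samples were 1 library of wild type N2 larvae and 1 library of larvae of a flp-6 mutant strain, both from whole L4 animals kept at 25 °C. Per the labels' protocols, total RNA was extracted with an organic reagent, checked on a Bioanalyzer and made into TruSeq version 2 libraries for Illumina sequencing. TopHat, Cufflinks and the genome build WBcel235 are named in the submitters' processing notes, with no version or setting. The deposited FPKM values, per the file headers 1 column per library, are normalized for transcript length and library size by the authors, and stranded counting is not given in the sources used here. The deposited log2 ratio of the authors is the log2 of the mutant FPKM over the N2 FPKM, without a pseudocount. It differed from that calculation by at most 5.33e-14. The deposited p-value and q-value of each gene come from the authors' comparison of 1 library with the other. The authors' tables of enriched terms hold a gene count and an enrichment p-value per term, per the file headers.

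The authors' table listed 0.0001 in place of 0. Among genes with a mean of at least 1 FPKM, 158 were listed at or under 0.0001 in the mutant library only and 162 in the N2 library only, and 116 of these 320 had a p-value of 1 in the authors' deposited table. No fold is given for such genes. The depth per library is unknown. For single-transcript protein-coding genes over 600 nt, FPKM times length was compared with whole multiples of a step. At the best step 22.9% of low values in the mutant library and 23.6% in N2 lay within 0.1 of a whole step, against 20% by chance, so no read counts were recovered and no counting interval is given. The locus field of the table often covers several neighbouring genes. Coordinates and lengths were therefore taken from the Ensembl annotation of WBcel235, release 115. It held 99.2% of the gene identifiers, and 88.3% of those genes lay inside their locus field within 60 bases.

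Differences are log2((mutant FPKM + 1)/(N2 FPKM + 1)), which understates the change of low genes. Genes with a mean FPKM over both libraries of at least 1 were kept, and a gene was counted as higher or lower at a 2-fold difference. With 1 library per genotype no test was made, no p-value was computed across genes, and the difference has no replicate check. The 39 gene lists, the size rule and the rule for named genes were fixed before the data were examined. The rule named flp-6, the 12 highest and 12 lowest genes with a mean of at least 5 FPKM, up to 4 members of each list with the largest differences, and any member of the thermosensory, steroid hormone and insulin signalling lists. Other genes named, among them daf-28, ins-31, ins-37, mtl-1, sod-3, dod-24 and R07C12.2, were chosen after their values were seen, as was the second ranking without genes at 0.0001. For each list of at least 4 measured members the median is given with a 95% bootstrap interval over its genes (2000 draws) and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. These describe the libraries and not the genotypes.

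For the length trend, the longest annotated transcript was used. The length-centred difference is the log2 difference minus the median of genes in the same of 40 length bins of equal size, over 12999 genes above 0.0001 in both libraries. It also removes any real change shared by genes of like length. Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM and a 4-fold threshold. Further ones fixed beforehand were rescaling to the same sum, the same upper quartile and a median difference of 0. That median was taken over genes with a mean of at least 5 FPKM. Length centring, leaving out genes at 0.0001 and protein-coding genes alone were added after the data had been seen.

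The calculations were tested on simulated data for the comparison of the mutant with N2. In 12999 genes with a length trend, 200 genes were changed 4-fold. Of these 88.5% were recovered at 2-fold as simulated and 93.5% after centring by length, with 682 and 4 unchanged genes past 2-fold. The simulated noise was the same at all expression levels and smaller than the spread of the real differences (SD 0.94). These counts therefore do not give the rate of false 2-fold calls in the real libraries. A recovery of 90% had been required of both kinds of value. The values as simulated missed it, and the requirement was then kept for the length-centred values only. A list with a small shift stood at percentile 100 in both. A single unshifted list stood at percentile 44.6 as simulated and, by chance, at 98.7 after centring. Over 400 unshifted lists of 30 genes, 4.50% lay outside the central 95% in each case. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.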

Results

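Total RNA from whole fourth-stage (L4) larvae of Caenorhabditis elegans grown at 25 °C was sequenced in 2 libraries. One library came from the wild type strain N2 and the other from a strain mutant for flp-6, a gene that encodes FMRFamide-like neuropeptides. The deposited table gave 1 FPKM value (fragments mapped to a gene, scaled to transcript length and library size) per library for 46233 genes. There were no replicates, so no value below has an error between animals or cultures, and every difference is one between 2 libraries. The sequencing depth of each library is unknown, because the FPKM values did not fall on steps of whole reads. The FPKM values summed to 989473 in the mutant library and to 1414572 in the N2 library.

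The first question was whether the mutant library held less of the targeted transcript. The flp-6 gene (WBGene00001449) lies on the forward strand of chromosome V from 9471975 to 9473792 in WBcel235, and its longest annotated transcript has 730 nt in 5 exons. It was listed at 4.40 FPKM in the mutant library and at 57.95 FPKM in the N2 library, so that the mutant value was 7.59% of the wild type value. The mutation is not described in the sources used here, so that whether the remaining 4.40 FPKM comes from parts of the gene outside it was not checked. The difference was -3.45 on the log2(FPKM + 1) scale, and it was the lowest of the 30 measured FLP neuropeptide genes. In the authors' deposited table, flp-6 had a p-value of 0.0012 and a q-value of 0.431, from a test that compares these libraries and not the genotypes.

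Across the transcriptome, the libraries were alike for most genes. Of 13436 genes with a mean of at least 1 FPKM, 10507 (78.2%) lay within 2-fold of each other, 1406 were at least 2-fold higher in the mutant library and 1523 at least 2-fold lower. Without genes at 0.0001 in either library, the counts of higher and lower genes were 1244 and 1365. Across the 13436 genes, which are not independent replicates, Pearson's r of the log2 values was 0.918 and Spearman's rho of the FPKM values was 0.912. The split of higher against lower genes depended on the scale. It was 48.0% higher as deposited, 87.0% with both libraries rescaled to the same sum and 68.8% with the same upper quartile. It was 66.7% with the median log2 difference of genes with a mean of at least 5 FPKM set to 0. After centring by transcript length it was 77.6%. The rescaling to the same sum moved the median of the 13436 genes by 0.44, the median setting by 0.18 and the upper quartile by 0.19 on the log2 scale. Under the median setting the median of the 13436 genes was thus 0.08 and not 0. Random lists, used below to place each gene list, come from the same libraries, so that a list's percentile does not depend on the scale except through the pseudocount.

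The direction of many genes went with transcript length. Among 12458 protein-coding genes above 0.0001 FPKM in both libraries, the median log2 difference was -0.57 for transcripts of 500 to 700 nt, -0.24 for those of 1000 to 1500 nt, 0.44 for those of 3000 to 4000 nt and 0.90 for those over 6000 nt. The shortest genes, up to 300 nt, had a median of -0.11. Spearman's rho of the log2 difference with length across genes was 0.379. For this reason each gene list of at least 4 measured members is given below with its median after removal of the length trend. This calculation was chosen after the data had been seen. The log2 difference also fell with expression, with a Spearman's rho of -0.280 with mean FPKM across the same genes. Centring by length makes no correction for that, whereas the random lists are matched on mean expression.

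**Figure D1:**
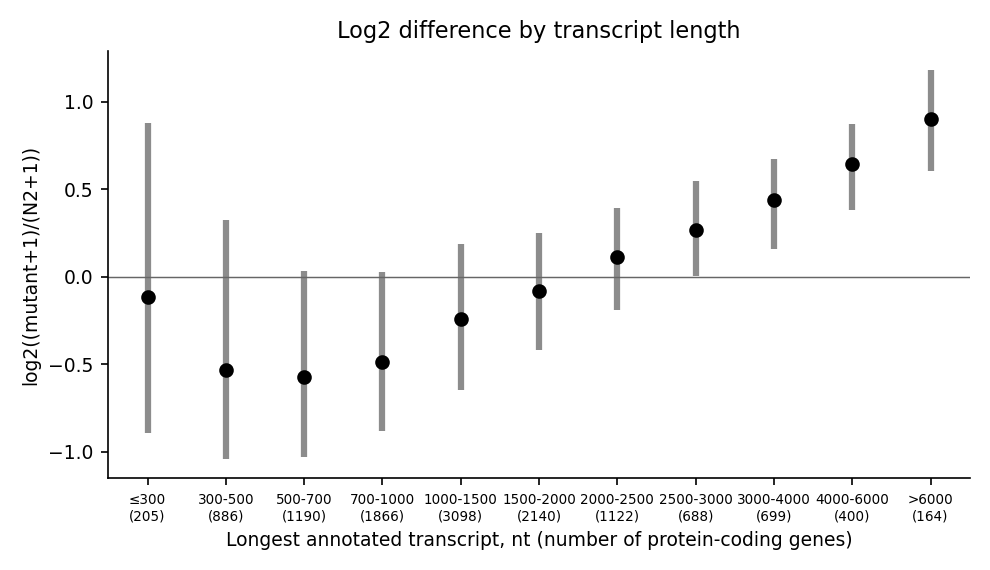
Log2 difference between the mutant and N2 libraries against the length of the longest annotated transcript, for protein-coding genes above 0.0001 FPKM in both libraries. Points are medians and grey bars the middle of the distribution from the lower to the upper quartile, with the number of genes in brackets. The median was -0.57 at 500 to 700 nt and 0.90 over 6000 nt.

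Sperm genes were higher in the mutant library. The major sperm proteins, the cytoskeletal proteins of the crawling nematode sperm, had a median log2 difference of 1.19 (95% bootstrap interval over genes 0.93 to 1.38), and 17 of 28 measured members were at least 2-fold higher and 0 at least 2-fold lower. Among them msp-19 had 37.2 FPKM in the mutant and 9.16 in the N2 library, msp-51 had 35.2 and 9.48, and msp-38 had 78.6 and 23.4. The msp-71 gene was listed at 2.88 FPKM in the mutant library and at 0.0001 FPKM in N2. The list of other sperm genes had a median of 0.93 (0.77 to 1.16), with 30 of 64 members at least 2-fold higher and 3 at least 2-fold lower. Its largest differences above 0.0001 FPKM in both libraries were sss-2, at 80.0 against 16.9 FPKM, and F32A11.3, at 42.8 against 9.42 FPKM. The members nspc-14 and nspc-13, from another group of nematode-specific peptides that the name pattern also took in, were listed at 0.0001 FPKM in the mutant library and at 14.03 and 5.28 FPKM in N2. Both lists stood at percentile 100 of 10000 random lists matched on expression. Their members are short, with median lengths of 384 and 389 nt, and after centring by length their medians were 1.52 and 1.20. Copies of the major sperm protein genes are nearly identical, so that the value of any single copy is uncertain.

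Protein phosphatase genes stood out in the authors' own list. In the authors' deposited table of terms, protein tyrosine phosphatase activity had 26 genes and an enrichment p-value of 1.61e-13, and the 24 identifiers given for it were all higher in the mutant library, with a median log2 difference of 1.45. Whether these genes belong to the male germ line was not tested. The authors' deposited table also placed 22 genes under protein serine/threonine kinase activity, of which 20 were higher (enrichment p-value 0.0685), with the muscle genes unc-22, unc-89 and ttn-1 and the cell cycle kinase cdk-1 among the members. It placed 4 under spermatogenesis, which were all higher (enrichment p-value 0.0462), namely cbp-1, fer-1, spe-8 and spe-15. Of these fer-1, spe-8 and spe-15 also fall under the name pattern of the list of other sperm genes. These terms were found among genes picked for their difference in these same libraries and are not independent evidence of a direction.

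Vitellogenins, the yolk proteins made in the intestine of adult hermaphrodites, were lower in the mutant library in 6 of 6 cases. Their median log2 difference was -0.96 (-1.25 to -0.60), at percentile 6.91 of random lists. The lowest was vit-1, with 704 FPKM against 1736 in N2, followed by vit-3 with 357 against 824 and vit-5 with 1340 against 2732. Their transcripts are long, with a median of 4935 nt, and long transcripts were mostly higher in this library. After centring by length the median was -1.77 (-2.06 to -1.35), at percentile 0 of random lists. The list of germ line and oocyte genes had a median of 0.30 (-0.04 to 0.55), at percentile 100, with 5 of 40 members at least 2-fold higher and 4 at least 2-fold lower. Among the lower members, rme-2 was listed at 0.0001 FPKM in the mutant library. The median length of the list was 1876 nt, and after centring by length its median log2 difference was 0.21 (0.11 to 0.45). In it mex-1, an RNA-binding protein of the early embryo, was higher at 120.9 against 45.7 FPKM, and syp-2, a synaptonemal complex protein, was lower at 60.7 against 169.0 FPKM.

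**Figure D2:**
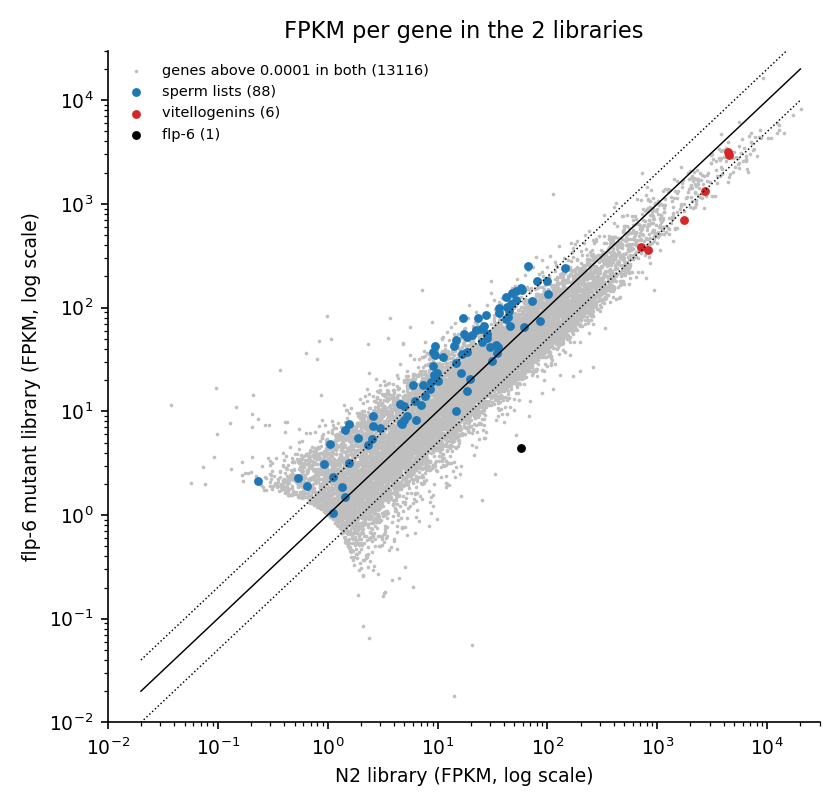
FPKM of each gene above 0.0001 FPKM in both libraries, N2 on the horizontal and the flp-6 mutant on the vertical axis, both on log scales. The solid line marks equal values and the dotted lines a 2-fold difference. Sperm genes (blue) lie mostly above the line, the 6 vitellogenins (red) lie below it, and flp-6 (black) lies at 4.40 against 57.95 FPKM.

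Neuropeptide genes as a class were lower in the mutant library. Of 30 measured FLP genes, 6 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.69 (-0.88 to -0.56) at percentile 0. Besides flp-6 the lowest were flp-19 at 1.70 against 8.43 FPKM, flp-26 at 3.19 against 12.7 FPKM and flp-1 at 9.14 against 27.2 FPKM. Of 61 measured NLP genes, 17 were at least 2-fold lower and 0 higher, with a median of -0.62 (-0.86 to -0.47). These are short genes, with median lengths of 637 and 533 nt, and after centring by length the medians were -0.16 (-0.35 to -0.01) for FLP and -0.15 (-0.35 to 0.15) for NLP genes. Most of the difference thus went with length, and the centred medians stood at percentiles 2.52 and 0.61 of random lists. Markers of neurons in general had a median of -0.29 (-0.43 to -0.12) at percentile 9.40, with none of 17 members past 2-fold. That median was -0.30 (-0.44 to -0.11) after centring by length, at percentile 0.845. It turned to 0.19 with both libraries rescaled to the same sum, which moves all genes upward and low ones less.

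Insulin-like peptide genes went both ways, with a few much higher and many lower. The ins-7 gene, an insulin-like peptide that acts as an agonist of the insulin receptor, was listed at 78.9 FPKM in the mutant library and at 19.01 in N2. The ins-8 gene had 7.64 against 0.129 FPKM and ins-37 had 9.21 against 2.75 FPKM. On the other side, ins-6, another agonist, had 0.673 against 6.23 FPKM, and daf-28 had 0.178 against 3.23 FPKM. In all, 3 of 26 measured members were at least 2-fold higher and 12 at least 2-fold lower, and the median was -0.93 (-1.31 to -0.51) at percentile 0. After centring by length 4 were higher and 5 lower by that rule, the median was -0.39 (-0.84 to 0.03) at percentile 0, and ins-7 stood at 2.33.

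**Figure D3:**
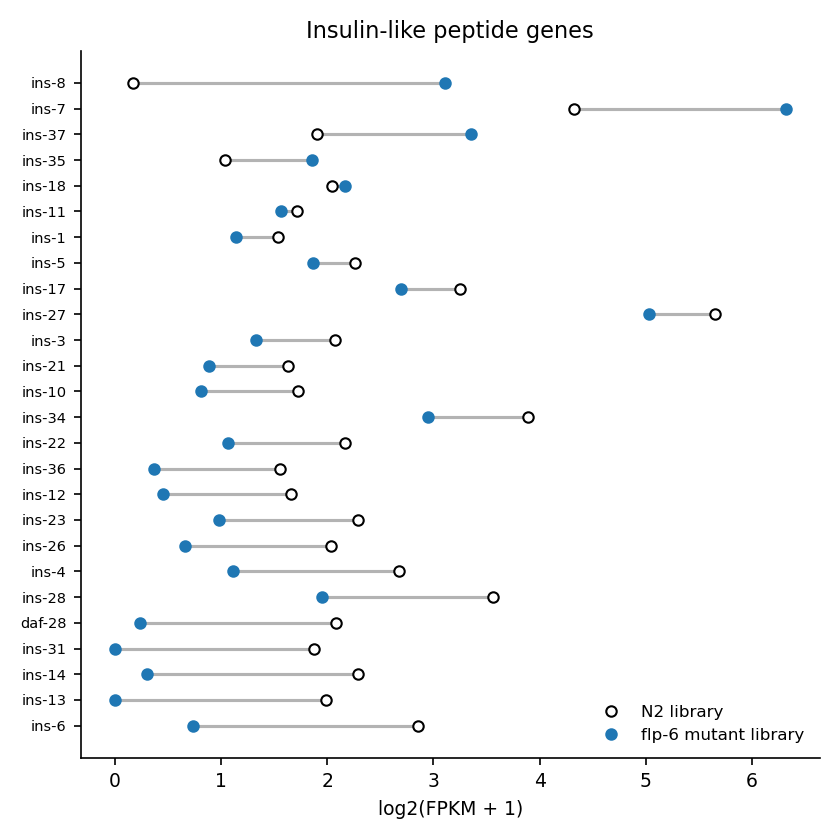
log2(FPKM + 1) of the 26 insulin-like peptide genes with a mean of at least 1 FPKM, in the N2 library (open circles) and the flp-6 mutant library (filled circles). The genes ins-8, ins-7 and ins-37 were at least 2-fold higher in the mutant library. The genes ins-13 and ins-31 were listed at 0.0001 FPKM there.

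The genes that receive and transmit the insulin signal differed little. Of 14 measured members of the pathway, 1 was at least 2-fold higher and 0 were lower, with a median of 0.21 (-0.17 to 0.55) at percentile 96.6, or -0.01 after centring by length. That member was daf-2, the insulin receptor, at 19.5 against 7.99 FPKM, a log2 difference of 1.19 that became 0.38 after centring by length. The forkhead transcription factor daf-16, which this receptor restrains, had 100.5 against 76.6 FPKM, and the phosphatase daf-18 had 133.0 against 84.0 FPKM. The kinases akt-1, at 101.8 against 115.5 FPKM, and akt-2, at 8.41 against 11.02 FPKM, were slightly lower as deposited.

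Known targets of daf-16 did not move as a block, yet held some of the largest single differences. Among genes that daf-16 induces, 2 of 16 were at least 2-fold higher and 5 to the same degree lower, with a median of -0.41 (-1.12 to -0.04) at percentile 16.3, or -0.25 (-0.69 to 0.32) after centring by length. Its sign turned with both libraries rescaled to the same sum. The metallothionein mtl-2 had 22.1 against 170.4 FPKM and mtl-1 had 0.684 against 4.25 FPKM. The mitochondrial superoxide dismutase sod-3 had 3.34 against 8.40 FPKM, whereas dod-6 was higher at 48.8 against 12.6 FPKM. Among genes that daf-16 represses, 4 of 10 were at least 2-fold higher and 3 lower, with a median of -0.56 (-1.05 to 1.93) at percentile 10.5, or -0.30 (-0.85 to 2.15) after centring by length. The dod-23 gene had 1260 against 113.3 FPKM, and a q-value of 0.112 in the authors' deposited table, equal to the lowest there. The dod-19 gene had 153.4 against 47.8 FPKM, dod-20 had 3.60 against 0.203 FPKM, and dod-24 was lower at 12.99 against 33.4 FPKM.

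Those genes of the temperature-sensing circuit and of steroid hormone signalling that could be measured lay within 2-fold. This applied to 8 of 8 measured members of the thermosensory list (AFD and AIY neurons), out of 18 with deposited values. It also applied to 8 of 8 of the dafachronic acid list, out of 11. The other members had a mean under 1 FPKM and could not be judged. In the first, the transcription factor crh-1 had 14.8 against 9.85 FPKM, ceh-14 had 5.06 against 5.73 FPKM, the calcineurin subunit tax-6 had 28.3 against 25.5 FPKM and ttx-7 had 131.8 against 197.2 FPKM. In the second, the nuclear receptor daf-12 had 6.96 against 5.27 FPKM, and the enzymes daf-9 and daf-36 of dafachronic acid synthesis had 0.961 against 1.20 and 15.8 against 14.2 FPKM. The medians of these lists were 0.28 (-0.15 to 0.54) at percentile 86 and 0.25 (0.01 to 0.57) at percentile 83.5, and turned to -0.09 and -0.15 after centring by length. Of the receptor guanylyl cyclases only 2 were measured, gcy-12 at 8.79 against 3.88 FPKM and gcy-28 at 57.1 against 39.7 FPKM. The gcy-8, gcy-18 and gcy-23 genes of the thermosensory list were thus not measured. All values come from whole larvae, so that they do not tell whether a gene differed within the AFD and AIY neurons.

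Cytosolic chaperone genes showed no heat shock pattern. Of 14 small and cytosolic heat shock genes, 0 were at least 2-fold higher and 1, hsp-43, was lower at 37.4 against 78.8 FPKM, and their median was 0.02 (-0.43 to 0.35) at percentile 84.8. Chaperones of the endoplasmic reticulum had a small positive median of 0.13 (0.05 to 0.34) at percentile 99.1, with hsp-3 at 492.6 against 293.3 FPKM. Of 16 members 13 were higher by any amount and 0 were past 2-fold. Mitochondrial chaperones and proteases had a median of 0.09 (-0.15 to 0.47) at percentile 92.7. After centring by length these 3 medians were 0.22 (-0.07 to 0.53), 0.15 (-0.06 to 0.23) and 0.13 (-0.07 to 0.21), at percentiles 94.2, 96.3 and 90.8.

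Innate immunity genes differed in both directions. Of 85 measured C-type lectins, 29 were at least 2-fold higher and 14 at least 2-fold lower, with a median of 0.44 (-0.37 to 0.82) at percentile 100. The median was 0.43 (-0.04 to 1.07) after centring by length and turned to -0.06 among members with a mean of at least 5 FPKM. The clec-60 gene had 36.5 against 0.634 FPKM and clec-82 had 31.7 against 0.799 FPKM, while clec-52 had 1.38 against 25.6 FPKM. Antimicrobial peptide genes had a median of -0.45 (-0.57 to -0.27), with 6 of 40 at least 2-fold lower, and lysozymes and saposin-like genes one of -0.52 (-0.73 to -0.32), with 7 of 30 lower. Both are short classes, and centring by length brought these medians to -0.02 and -0.08. The saposin-like genes spp-23, at 9.42 against 42.9 FPKM, and spp-4, at 28.5 against 116.5 FPKM, had the lowest differences.

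Further classes of short genes had medians below 0 as deposited. The cytosolic ribosomal protein genes, with a median length of 513.5 nt, had a median of -0.75 (-0.92 to -0.60), and 28 of 79 were at least 2-fold lower, rpl-22 among them at 1617 against 4394 FPKM. They took 20.7% of the FPKM sum in the mutant library and 26.8% in N2. Histone genes had a median of -0.72 (-1.01 to -0.34), with 9 of 26 lower, and oxidative stress enzymes one of -0.61 (-0.96 to -0.19), with sod-2 at 160.6 against 396.3 FPKM. The glutathione S-transferases had a median of -0.54 (-0.76 to -0.23), with gst-1 at 271.3 against 850.2 FPKM. After centring by length these 4 medians were -0.26, -0.28, -0.24 and 0.00, at percentiles 9.76, 0.72, 7.79 and 38.4.

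Of the classes whose members are of middle length, cytochrome P450 genes (median 1631 nt) had a median of -0.45 (-0.62 to -0.15), and cyp-25A1 was lowest at 1.23 against 9.06 FPKM. After centring by length the median was -0.34 (-0.55 to -0.05), at percentile 0 of random lists. Moulting and apical matrix genes (1864 nt) had a median of -0.41 (-0.56 to -0.20), with noah-1 at 2.33 against 7.36 FPKM, and -0.27 (-0.45 to -0.16) after centring, again at percentile 0. Cuticle collagens (1023 nt) had a median of -0.38 (-0.49 to -0.31) at percentile 0.13, which centring brought to -0.04 (-0.11 to 0.10) at percentile 13.3. Rescaling both libraries to the same sum moves all genes upward and low ones less. It turned the medians of cytochrome P450 genes and collagens to 0.01 and 0.05. Body wall muscle markers were higher, with a median of 0.32 (0.01 to 1.19) at percentile 99.98, and 5 of 15 were at least 2-fold higher. They included the giant protein unc-22 at 8.23 against 0.883 FPKM, and the myosins unc-54 at 393.1 against 127.8 and myo-3 at 50.8 against 15.7 FPKM. These members have transcripts of over 6000 nt, and 1 of 15 was at least 2-fold higher after centring by length, with a median of 0.57 (0.38 to 0.69). Markers of pharyngeal muscle and glands had a median of 0.73 (0.27 to 0.79), with C49G7.3 at 28.8 against 4.51 FPKM. This median was 0.25 at a mean of at least 5 FPKM and 0.26 with a pseudocount of 5, and after centring by length it was 0.57 (-0.04 to 1.35).

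Several further lists had small medians. These were -0.16 for UDP-glucuronosyltransferases, -0.24 for fatty acid synthesis and desaturation, -0.16 for lipases and beta-oxidation, -0.25 for autophagy and lysosome genes and -0.19 for serpentine receptors, and after centring by length -0.09, 0.05, -0.08, -0.17 and -0.10. All 5 lay within the central 95% of random lists both before and after centring. Nuclear hormone receptors had a median of -0.12 (-0.17 to -0.07) at percentile 2.05, with 2 of 155 at least 2-fold higher and 0 lower, and 0.03 (-0.03 to 0.08) after centring. F-box and MATH-BTB genes had one of -0.20 (-0.32 to -0.11) at percentile 0.13, with 7 of 182 higher and 28 lower, and 0.06 (-0.05 to 0.15) at percentile 18.1 after centring, with 12 higher and 13 lower. The sign of these 7 medians also turned with both libraries rescaled to the same sum, as a shift of that size turns any small negative median. Heterochronic genes had a median of 0.27 (-0.14 to 0.76), with lin-41 at 84.8 against 32.6 FPKM, and -0.10 after centring by length. Intestinal markers had one of 0.07 (-0.56 to 0.46) at percentile 97.8, and 0.00 (-0.31 to 0.33) at percentile 78.7 after centring. The only member matched in the mitochondrially encoded list was ctb-1, which was lower at 2620 against 6426 FPKM, a log2 difference of -1.29.

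**Figure D4:**
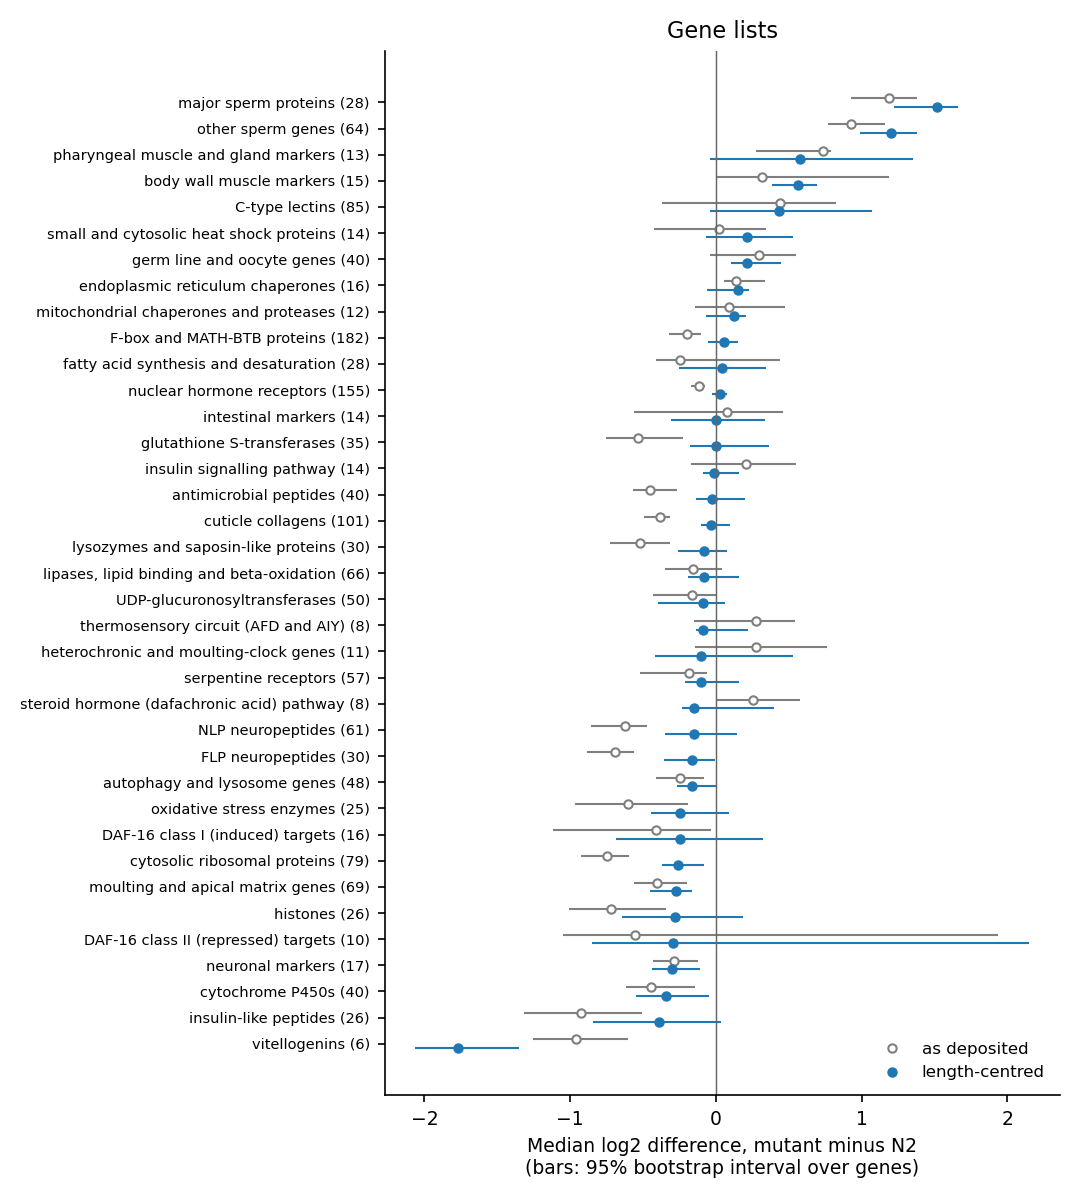
Median log2 difference (mutant minus N2 library) of 37 gene lists fixed before the data were examined, as deposited (open circles) and after centring by transcript length (blue circles), with 95% bootstrap intervals over the genes of each list and the number of measured genes in brackets. The major sperm proteins are highest and the vitellogenins lowest in both. With both libraries rescaled to the same sum, 11 of the 37 medians as deposited change sign, cuticle collagens and cytochrome P450s among them.

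The fixed rule for single genes named the 12 highest and 12 lowest differences among genes with a mean of at least 5 FPKM. All 24 were listed at 0.0001 FPKM, which stands in place of 0, in 1 of the libraries, and no fold is given for them. The ribosomal protein gene rpl-35 was listed at 0.0001 in the mutant library and at 3515 FPKM in N2, the aspartyl protease gene asp-1 at 0.0001 and 1961, the trafficking gene rab-11.1 at 0.0001 and 192.3, and the yolk receptor gene rme-2 at 0.0001 and 135.7. In the opposite direction, pqn-59 was listed at 339.1 FPKM in the mutant library and at 0.0001 in N2, skr-1, a ubiquitin ligase component, at 325.1 and 0.0001, and pdha-1, a subunit of pyruvate dehydrogenase, at 321.0 and 0.0001. Of these 24 genes, 15 had a p-value of 1 in the authors' deposited table.

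The same ranking was therefore repeated, after the values had been seen, for protein-coding genes above 0.0001 in both libraries. The highest were B0348.2 at 82.9 against 0.977 FPKM, T19C9.8 at 47.8 against 0.840, ZC239.22 at 49.4 against 1.08, clec-60, R07C12.1 at 25.2 against 0.371, F49F1.5 at 148.8 against 7.16 and clec-82. The lowest were pud-3 at 0.0561 against 20.8 FPKM, the channel gene ocr-1 at 0.0179 against 14.1, clec-52, flp-6, and T24B8.5, an immune gene, at 2.49 against 33.1 FPKM. Next came mtl-2, fipr-17 at 1.53 against 16.4 FPKM and F23A7.4 at 148.9 against 926.1 FPKM. In the library where they were lower, B0348.2, T19C9.8, clec-60, R07C12.1, clec-82, pud-3 and ocr-1 had less than 1 FPKM. The counting error of such low values is unknown, so that the size of these differences is uncertain. Whether pud-3 and ocr-1 truly differed more than flp-6 stays open.

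In the authors' deposited table of selected genes, 715 genes had a p-value under 0.05, of which 424 were higher and 291 lower in the mutant library. In the authors' deposited table of all genes the lowest q-value was 0.112, and 0 genes were marked significant. The higher genes of the authors' deposited table had a median transcript length of 1387 nt and the lower ones of 691 nt, against 1256 nt for all genes with a mean of at least 1 FPKM.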

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

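Length centring, leaving out genes at 0.0001 and protein-coding genes alone were chosen after the data had been seen. The other alternatives were fixed beforehand. The cause of each shift below was not tested. Setting the median to 0 moves every gene alike. The other rescalings move all genes the same way, but low genes less because of the pseudocount. Rescaling to the same sum moved the median of pharyngeal markers from 0.73 to 0.93 and that of germ line genes from 0.30 to 0.81. The flp-6 difference stayed between -3.69 and -2.74 under its 7 alternatives. Counts of genes at least 2-fold higher and lower, 1406 and 1523 as reported, were 480 and 950 with a pseudocount of 5 and 2644 and 396 with both libraries rescaled to the same sum. A 4-fold threshold gave 217 and 160. With a mean of at least 5 FPKM 749 genes were higher. The lower count was 917 with the median of genes with a mean of at least 5 FPKM set to 0. It was 860 with the same upper quartile and 409 after length centring, against 1413 higher genes. The remaining counts stayed within 1.5 times. The sperm lists, vitellogenins and insulin-like peptides kept their direction under every alternative run. No paired analysis was possible because each genotype has 1 library. Every symbol had 1 row, so that taking the highest row per symbol changed no value. The column that marks significant genes read "no" for every gene, and no column gave the status of each test. Restricting to completed tests was therefore not run. Depth is unknown, which leaves the counting error of low genes open.

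Medians of lists outside the central 95% of random lists moved beyond their bootstrap interval, or turned, as follows. With a pseudocount of 5 they were -0.50 for FLP genes, -0.40 for NLP genes, -0.40 for insulin-like peptides, -0.21 for glutathione S-transferases, -0.25 for collagens, -0.19 for moulting genes, 0.91 for major sperm proteins, 0.66 for other sperm genes, 0.26 for pharyngeal markers, -0.063 for nuclear hormone receptors and -0.10 for F-box genes. A pseudocount of 0.1 gave -1.35 for insulin-like peptides and 0.85 for pharyngeal markers. Without a filter they were -0.076 for cytochrome P450s, 0.00 for C-type lectins, -0.14 for antimicrobial peptides, -0.17 for collagens, -0.11 for moulting genes, 0.54 for other sperm genes, 0.00 for histones, -0.016 for intestinal markers, -5.6e-05 for nuclear hormone receptors and -0.0038 for F-box genes. A mean of at least 5 FPKM gave -0.058 for C-type lectins, 0.25 for pharyngeal markers and -0.68 for F-box genes.

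Rescaling to the same sum gave -0.20 for FLP and -0.18 for NLP genes, 0.64 for chaperones of the endoplasmic reticulum, -0.19 for oxidative stress enzymes, -0.14 for glutathione S-transferases, 0.011 for cytochrome P450s, -0.022 for antimicrobial peptides, 0.046 for collagens and -0.031 for moulting genes. It gave 1.67 for major sperm proteins, 1.34 for other sperm genes, 0.81 for germ line genes, -0.31 for histones, -0.23 for ribosomal proteins, 0.93 for pharyngeal and 0.56 for intestinal markers, 0.27 for nuclear hormone receptors and 0.18 for F-box genes. With the median of genes with a mean of at least 5 FPKM set to 0 the values were -0.51 for FLP and -0.44 for NLP genes. They were -0.20 for collagens, -0.57 for ribosomal proteins, 0.91 for pharyngeal markers, 0.063 for nuclear hormone receptors and -0.016 for F-box genes. The same upper quartile gave -0.48 for FLP and -0.42 for NLP genes, 0.36 for chaperones of the endoplasmic reticulum, -0.21 for collagens, 1.41 for major sperm proteins, -0.52 for ribosomal proteins, 0.88 for pharyngeal markers, 0.056 for nuclear hormone receptors and -0.037 for F-box genes. Length centring gave -0.16 for FLP and -0.15 for NLP genes, -0.39 for insulin-like peptides, 0.00 for glutathione S-transferases, -0.025 for antimicrobial peptides, -0.036 for collagens, 1.52 and 1.20 for the sperm lists, -0.28 for histones, -0.26 for ribosomal proteins, 0.027 for nuclear hormone receptors and 0.056 for F-box genes.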

Other observations

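All tests in this part were chosen after the results they bear on had been seen. A run of neighbouring genes on chromosome IV was higher in the mutant library. Between 4119460 and 4157185, F49F1.5 had 148.8 against 7.16 FPKM, R07C12.2 had 72.8 against 8.85, R07C12.1 had 25.2 against 0.371 and K08D10.14 had 45.1 against 2.31 FPKM. That is 4 genes with a length-centred difference of at least 2 within 10 consecutive measured genes, of 227 such genes in the genome. The same number was reached at 2 places on this chromosome, and 4 was also the 95th percentile of the highest number over 1000 shuffled gene orders, so that by this count the run does not stand apart from chance. All 10 consecutive genes from F49F1.1 to scrm-8 were higher, however, with length-centred differences from 0.89 to 4.75, and 9 of them had one of at least 1, as had 10.9% of all genes. A window with as many was found at 2 places in the genome and in 1 of 1000 shuffled orders. This second count was added after the values of the run had been seen. Shuffling also breaks up neighbours that are regulated together or alike in sequence, and the cause of the run was not tested.

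The 12 measured protein-coding genes of the mitochondrial genome were all lower in the mutant library, with a median log2 difference of -1.14, or -0.87 after centring by length. In the neighbourhood of the mutated gene, 37 of 292 genes within 1 Mb of flp-6 (12.7%) had a length-centred difference of at least 1 either way, against 1784 of 12706 elsewhere (14.04%). In the authors' deposited table of terms, 5 RNA polymerase subunit genes were all lower, with an enrichment p-value of 0.0107. Their median length was 573 nt, and their median log2 difference was -1.46, or -0.85 after centring.

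Long genes were higher and short genes lower in the mutant library. The medians of the length bins spanned 1.47 on the log2 scale, which a single factor between the libraries cannot give. The trend was also not limited to the listed gene classes, since Spearman's rho across the 10990 protein-coding genes in no list was 0.390. A bias by gene length between the libraries, from RNA integrity, fragment sizes or the estimation of FPKM, is a candidate explanation, and the trend was present in each of 4 expression classes of equal size, with rho from 0.165 to 0.560. An effect of the genotype on length itself was not tested and stays open.

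Sperm genes were higher in the mutant library against the length trend. Protein-coding transcripts of 300 to 500 nt had a median of -0.53, so that removal of the trend was bound to raise most sperm genes. The length-centred median of 88 sperm genes was 1.24 (95% bootstrap interval 1.19 to 1.44) and is thus no separate test. That sperm genes were mostly higher where genes of like length were mostly lower speaks against gene length as the cause. The 17 members named spe, which are not multi-copy families, had a median of 1.20 (0.884 to 1.60), so that reads shared between near-identical copies may affect single msp values but do not account for the class. A difference in developmental timing between the cultures is a candidate explanation. The vitellogenins, which come on in adults, had a length-centred median of -1.77 (-2.06 to -1.35), though as deposited they stood at percentile 6.91. A shift in either direction had been taken to go with timing. The germ line and oocyte list went the other way, at 0.21 (0.11 to 0.45) after centring. These lists therefore do not settle the question. With 1 culture per genotype, timing and an effect of flp-6 cannot be told apart.

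Of the protein-coding genes with a mean of at least 20 FPKM, 22 were listed at 0.0001 in 1 library. Loss of expression in the mutant is argued against as the common cause, since 14 of them were at 0.0001 in the N2 library and 8 in the mutant. Failed estimates are a candidate explanation, because 20 of the 22 (90.9%) had a p-value of 1 in the authors' deposited table, against 0.0511% of 5867 genes of like level above 0.0001 in both libraries. Whether any single one of them, such as rme-2, was truly silent in 1 library stays open.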
